A study of Homo sapiens with 19 samples.

How the data were processed

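The series holds 1 array for each of 19 human breast tumours, 5 labelled triple-negative and 14 labelled non-triple-negative, all collected before treatment per the labels. Total RNA was extracted with a spin-column kit and labelled with biotin by a whole-transcript sense-target protocol, per the labels' protocols. The deposited table gives 1 intensity value on a linear scale for each of 33297 probe sets and each array. Affymetrix Expression Console is named in the submitters' processing notes. Its version, the summarisation and normalization method and any background step are not given in the sources used here, and the linear scale was read from the values themselves. The table carries no detection calls, so no value could be marked as above or below background, and 1.85% of values lay below 1 (1.05% to 3.26% per array).

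Group and replicate were taken from the labels. Each array is labelled as a separate tumour, so p-values measure the spread between tumours of a group. Replicate numbers were given in accession order within each group and pair nothing across groups. Probe sets were paired with genes through the platform annotation supplied with the table: 19460 probe sets had 1 gene symbol, 1754 had several and 12083 had none, and only the first kind was used. Symbols were updated by gene ID through the RefSeq gene table of assembly GRCh38.p14, which matched 19429 of 19460. No coordinates are given, since the sources used here name no genome build. XIST, TSIX and Y-linked genes (24 probe sets) were left out of every step. Of genes with several probe sets (768) the 1 with the highest mean over all arrays stood for the gene, which left 18394 genes.

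Values below 1 were set to 1 and log2 was taken. A rule set before the data were examined kept the deposited scale if array medians differed by less than 0.2 on the log2 scale and centred each array on its median otherwise. They differed by 0.230, so arrays were centred. The groups gave no difference past the threshold in the mean correlation with the other arrays, the share of values below 1 or the median before centring (exact permutation p = 0.243, 0.298 and 0.956).

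Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 27 gene lists hold 458 members, of which 413 had a probe set of their own, and the others were not analysed here. Lists were tested with limma's camera at its preset correlation of 0.01, with an estimated correlation and fry as alternatives. Each list also received a score per tumour, the mean over its members of the log2 value minus the gene's mean over 19 tumours. Scores were compared by a two-sided exact permutation test over all 11628 splits of 19 tumours into 5 and 14, adjusted over the 27 lists. The same exact test was run for every gene. Counts adjusted over the list alone use Benjamini-Hochberg within the list.

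The genes named were, in each direction, up to 12 with the largest difference among those past the threshold. Where fewer than 6 passed, the 6 with the smallest unadjusted p were named instead, without a claim that they passed. Added to these were a fixed set with FZD7, LRP6, receptor, luminal, basal and proliferation genes, of which 4 were not analysed here, and up to 4 members with the smallest p of each list described. XIST, TSIX, Y-linked genes, immunoglobulin and T cell receptor segments and probe sets with several genes were never named. Genes named outside this rule are said to be so, apart from FZD5, FZD6 and FZD10 of the frizzled list and the named members of the cilia list.

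The alternatives were an intensity trend with robust variances, array weights, a spread per group, quantile normalization, the mean of a gene's probe sets, all probe sets, leaving out the dimmest 30% or 50% of genes, stroma or immune list scores as covariates, and leaving out each tumour in turn. Added after seeing the data were log2(value + 16), the exact permutation test for every gene, and values as deposited without centring. Median centring, listed as an alternative beforehand, became the main setting by the rule above.

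The tests were tried on simulated data for 18394 genes and the same group sizes, with 200 genes changed in each of 5 runs. At an adjusted p under 0.05 limma recovered 39.7% of genes changed by 1 on the log2 scale, 85.1% of those changed by 2 and 94.5% of those changed by 3, and 35 of 773 calls were false. Camera called the shifted list in 5 of 5 runs and 0 of 130 unshifted lists, and the score test 5 of 5 and 3 of 130. The simulated genes were independent of each other, unlike genes in tumours.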

Results

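RNA from 19 human breast tumours, sampled before treatment, was hybridised to whole-transcript expression arrays, with 1 array per tumour. The labels call 5 tumours triple-negative, which means breast cancers scored as lacking the estrogen receptor, the progesterone receptor and HER2, and call the other 14 non-triple-negative. The labels do not state which receptors each non-triple-negative tumour carried. The title of the series names FZD7, a cell surface receptor for Wnt ligands, in the proliferation of triple-negative cancers, so the comparison of the groups asks how the genes of these tumours differ and where FZD7, the Wnt pathway and the cell cycle stand among them. Array medians, as deposited, lay between 123.9 and 145.3, and pairs of arrays correlated at r = 0.803 to 0.936 across probe sets. The number of arrays, above all the 5 triple-negative ones, limits the precision of every difference. All differences are log2 values in triple-negative minus non-triple-negative tumours with the standard error, and means are given ± SD with n = 5 and n = 14.

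The receptor genes separated many, not all, of the tumours in the direction of the labels. ESR1, which encodes estrogen receptor alpha, averaged 5.47 ± 0.81 in the triple-negative tumours and 8.88 ± 2.96 in the others, a difference of -3.42 (SE 1.25; limma adjusted p = 0.421). PGR, the progesterone receptor gene, averaged 5.40 ± 1.35 against 7.12 ± 2.71 (difference -1.72, SE 1.17; adjusted p = 0.679). ERBB2, which encodes HER2, averaged 8.02 ± 1.20 against 9.65 ± 1.98 (difference -1.64, SE 0.88; adjusted p = 0.592). None of the 3 passed the threshold over all genes, and averaging the probe sets of a gene gave ESR1 a difference of -1.83. Of the 14 non-triple-negative tumours, 10 exceeded every triple-negative tumour in ESR1, 8 in PGR and 7 in ERBB2, and 3 did so in ERBB2 without doing so in ESR1. In ERBB2, 3 tumours lay between 12.57 and 13.73 and the remaining 11 at 9.58 or below. The same 3 tumours had the highest values of GRB7, a neighbour of ERBB2 that is often co-amplified with it, at 10.32 to 12.63. In total 13 of the 14 exceeded all triple-negative tumours in at least 1 receptor gene, and 1 did so in none.

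**Figure D1:**
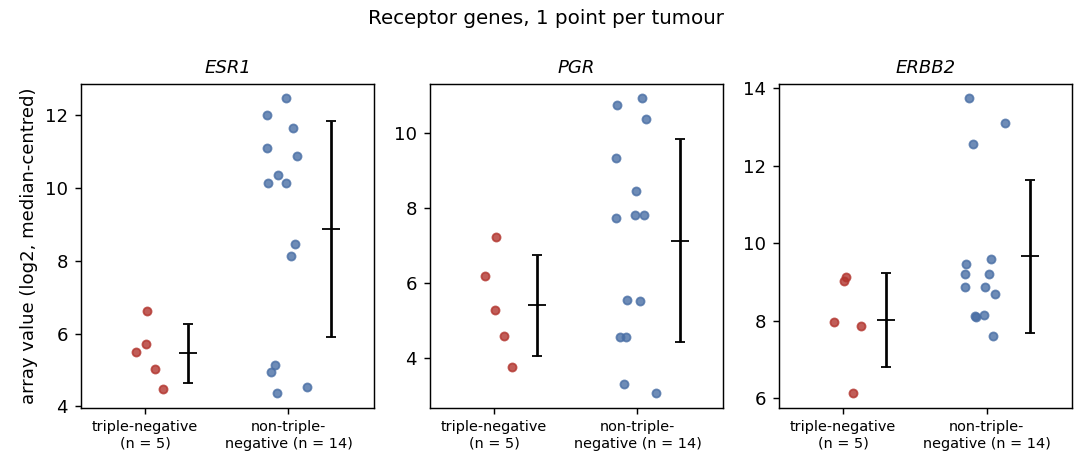
ESR1, PGR and ERBB2 array values on the log2 scale (vertical axes), 1 point per tumour, for 5 triple-negative and 14 non-triple-negative tumours, with black bars for the group mean ± SD. Triple-negative values of ESR1 lie between 4.46 and 6.64, and 10 of the 14 other tumours lie above them.

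FZD7 was 2.48-fold higher in the triple-negative tumours, at 8.91 ± 0.68 against 7.60 ± 0.74, and 9 of the 14 non-triple-negative tumours lay below the lowest triple-negative value. The difference of 1.31 (SE 0.36, 95% interval 0.55 to 2.07) did not pass over all genes (limma adjusted p = 0.331; exact permutation p = 0.00335, two-sided, 0.433 adjusted over all genes). LRP6, a co-receptor that forms a complex with frizzled proteins, differed by 0.87 (SE 0.28; adjusted p = 0.392). In triple-negative tumour 4 it was 8.45, and only 1 of the 14 non-triple-negative tumours lay below that value. Its difference was 0.67 without triple-negative tumour 5 and 1.21 without triple-negative tumour 4. FZD7 and LRP6 were the only 2 of the 16 frizzled and Wnt co-receptor genes higher when adjusted over the list alone, at adjusted p = 0.0279 and 0.0482, and none passed over all genes. Another 4, ROR1 (1.25, SE 0.46), PTK7 (0.96, SE 0.42), FZD10 (0.42, SE 0.20) and FZD5 (0.90, SE 0.43), were higher only at an unadjusted p under 0.05. FZD5 stood at 8.41 and 9.21 in triple-negative tumours 2 and 3. In the other triple-negative tumours it was 5.92 to 6.70, within the 5.26 to 7.70 of the non-triple-negative ones. ROR1 encodes a receptor for Wnt5a. The title of the series names FZD7, and where a gene is chosen on the same samples neither its test nor that of its list is independent evidence of direction. In the list as a whole 12 of 16 members were higher, and camera, which compares a list with all other genes, called it higher (adjusted p = 0.0029). With an estimated correlation between genes the list gave adjusted p = 0.163. In fry, another limma list test, the list gave adjusted p = 0.0947 for a shift in 1 direction and 0.0331 for change in either direction. It was the only 1 of 27 lists past the threshold in the latter.

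**Figure D2:**
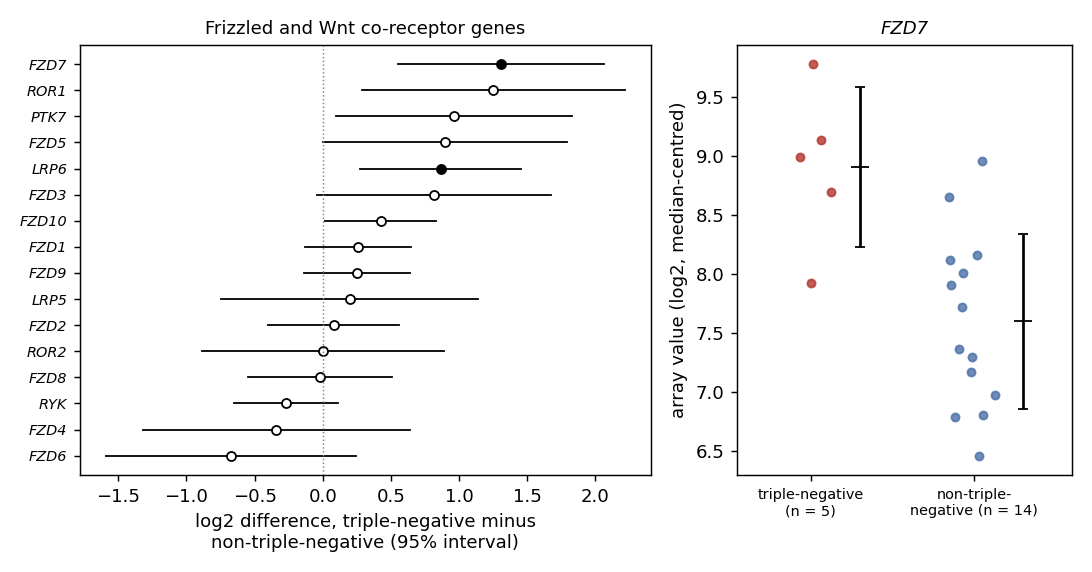
Left, log2 difference (horizontal axis) of each of 16 frizzled and Wnt co-receptor genes with its 95% interval, filled where the gene passed adjusted over the list alone; right, FZD7 array values on the log2 scale per tumour with the group mean ± SD. FZD7 has the largest difference of the list, 1.31, and FZD6 the lowest, -0.68.

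Other parts of the Wnt pathway gave differences in both directions. The 13 Wnt antagonists, most of them secreted, were higher in camera (adjusted p = 0.0309; adjusted p = 0.247 with an estimated correlation), with 8 members higher and 5 lower. WIF1, which binds Wnt ligands outside the cell, was higher by 2.91 (SE 0.75) and was the only member past the threshold adjusted over the list alone (adjusted p = 0.0114). SFRP1, which is counted among the basal genes as well, differed by 2.78 (SE 1.01) and SFRP5 by 0.54 (SE 0.21). DKK1, which blocks LRP6, differed by -2.55 (SE 1.22). The call of the list was lost without triple-negative tumour 3 (adjusted p = 0.113), triple-negative tumour 4 (0.224) or non-triple-negative tumour 7 (0.0505), and with the immune score as a covariate (mean difference 0.32, adjusted p = 0.211). The 19 Wnt ligand genes gave a median difference of 0.13 and a mean of -0.01, opposite in sign (camera adjusted p = 0.371), and were called higher with the lowest 30% of genes left out (mean 0.22, adjusted p = 0.0123) or the lowest 50% (0.19, adjusted p = 0.0329). Of 18 measured beta-catenin cofactors and Wnt target genes, BMP4 alone passed adjusted over the list alone (-0.95, SE 0.27; adjusted p = 0.0421), and the list had a mean difference of 0.01 (camera adjusted p = 0.702). In this list CCND1, which encodes cyclin D1, differed by -1.68 (SE 0.67), TCF7L1 by 1.21 (SE 0.58) and MYC by 0.71 (SE 0.48).

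By mean difference with all tumours in the fit, luminal genes stood furthest from 0 among the 27 lists. Without triple-negative tumour 5 the B and plasma list stood further, at 2.13 against -1.83 for luminal genes. All 23 luminal and estrogen receptor genes had lower means in the triple-negative tumours, with a median difference of -1.95, and 13 of them were lower adjusted over the list alone, though none over all genes. Among them were FOXA1 (-2.64, SE 0.80) and MYB (-2.44, SE 0.69), both transcription factors of estrogen-responsive cells, NAT1, an arylamine acetyltransferase (-2.31, SE 0.70; all 14 non-triple-negative tumours above the highest triple-negative one), and AGR2, a secretory pathway protein (-4.76, SE 1.52). GATA3, another luminal transcription factor, differed by -1.33 (SE 0.74; adjusted p = 0.607 over all genes), -0.46 with the immune score as a covariate and -1.83 with array weights. Camera called the list lower (adjusted p = 2.62e-13), and its adjusted p was 0.247 with an estimated correlation. The score of the list, the mean centred log2 value of its members, averaged -1.56 ± 1.06 against 0.56 ± 1.64 (exact permutation p = 0.0171, 0.154 adjusted over the 27 lists). The 12 genes of the ERBB2 neighbourhood, 11 of them lower, were called lower in camera (adjusted p = 0.00665; adjusted p = 0.734 with an estimated correlation), with PGAP3 at -1.47 (SE 0.76), GRB7 at -1.77 (SE 0.97) and MIEN1 at -1.11 (SE 0.72). None of the 12 passed adjusted over the list alone. The score of this list was 1.97 to 3.54 in the 3 tumours with the highest ERBB2, non-triple-negative 1 to 3. In the remaining 11 it was -0.89 to 0.16, against -1.04 to -0.39 in the triple-negative tumours.

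Epithelial adhesion genes were lower in camera (adjusted p = 0.00615; adjusted p = 0.607 with an estimated correlation), 11 of 12 measured members having the lower mean. The tight junction genes MARVELD2 (-1.05, SE 0.36) and CLDN7 (-1.37, SE 0.48) had the smallest p, followed by RAB25 (-0.66, SE 0.37) and GRHL2 (-0.64, SE 0.36), and none passed adjusted over the list alone. This call was lost without triple-negative tumour 2, whose score was -1.76 against -0.14 to -0.05 in the other triple-negative tumours: without it the mean difference was -0.22 rather than -0.56 and camera's adjusted p = 0.391. The same tumour had the highest T and NK score (2.51) and B and plasma score (2.72) of all 19. The call was lost with the immune score as a covariate as well, at -0.24 (adjusted p = 0.448). Mesenchymal transition genes had a mean difference of 0.07 (camera adjusted p = 0.269), between 0.0021 without non-triple-negative tumour 7 and 0.16 without non-triple-negative tumour 6. Hypoxia genes were called lower (camera adjusted p = 0.0358; adjusted p = 0.807 with an estimated correlation), with the glycolytic genes ALDOA at -0.87 (SE 0.34) and LDHA at -0.53 (SE 0.23), PFKFB3 at -0.79 (SE 0.41) and P4HA1 at -0.55 (SE 0.35). None of the 14 measured hypoxia genes passed adjusted over the list alone. The hypoxia call was lost without any of 8 tumours taken singly, triple-negative 1 to 4 and non-triple-negative 1, 2, 3 and 14, with adjusted p of 0.0533 to 0.157, and with the immune score as a covariate (-0.30, adjusted p = 0.112) or the lowest 30% of genes left out (-0.36, adjusted p = 0.0690).

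Basal epithelial genes stood higher as a list, with all 14 measured members higher in mean (camera adjusted p = 0.00669; adjusted p = 0.607 with an estimated correlation), and none passed adjusted over the list alone. SOX10, a neural crest and myoepithelial transcription factor, differed by 2.26 (SE 0.77), VGLL1 by 1.88 (SE 0.65) and SFRP1 by 2.78 (SE 1.01). The keratins KRT5 and KRT14, EGFR and KIT gave smaller differences, and of the 21 members of the list 14 were measured. KRT5 differed by 0.66 (SE 1.20), KRT14 by 0.30 (95% interval -1.79 to 2.38), EGFR by 0.36 (SE 0.87) and KIT by 1.04 (SE 0.89). Of all 19 tumours, non-triple-negative tumour 14 had the highest basal score (2.64), the highest KRT5 value (13.26) and the lowest luminal score (-3.08). Its ESR1 (4.37), PGR (4.56) and ERBB2 (8.12) values did not exceed the highest triple-negative ones (6.64, 7.21 and 9.11). The labels do not say which receptor it carried, and its label was kept. KRT5 and KRT14 turned to -0.16 and -0.15 with array weights, KRT14 to -0.23 without triple-negative tumour 4, and EGFR to -0.16 with the immune score as a covariate. Leaving out 1 tumour moved KRT5 between 0.083 (without triple-negative 4) and 1.52 (without triple-negative 2), and EGFR between 0.089 (without non-triple-negative 7) and 0.69 (without non-triple-negative 14). The call of the list was lost without triple-negative tumour 3 (adjusted p = 0.0804) and with the immune score as a covariate (mean difference 0.67, adjusted p = 0.0719). The 12 luminal progenitor genes, which share KIT with the basal list, were not called (camera adjusted p = 0.0519), but ELF5, a transcription factor of the alveolar lineage, was higher adjusted over the list alone, by 3.86 (SE 1.20; adjusted p = 0.0496). TNFRSF11A differed by 1.01 (SE 0.39), CSN3 by 1.98 (SE 1.25; 0.53 without triple-negative tumour 5 and 0.41 with array weights) and CD24 by -0.92 (SE 0.54; -0.61 without triple-negative tumour 2). The progenitor list was called in 6 of the 19 fits that each left out 1 tumour: without triple-negative 2 or 4 or non-triple-negative 8, 9, 12 or 14, with adjusted p of 0.0121 to 0.0463.

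Lymphocyte marker lists had higher means in the triple-negative tumours and were called by camera with its preset correlation alone. All 12 measured B and plasma cell markers had the higher mean, with a median difference of 1.63, and 11 were higher adjusted over the list alone, though none over all genes. MS4A1, which encodes the B cell antigen CD20, was higher by 2.99 (SE 0.83), CD79A of the B cell receptor by 2.36 (SE 0.65), BANK1 by 2.12 (SE 0.64) and the B cell coactivator POU2AF1 by 0.73 (SE 0.22). Camera called the list higher (adjusted p = 3.10e-12), and its adjusted p was 0.163 with an estimated correlation. Its score was 1.26 ± 1.18 against -0.45 ± 0.97 (exact permutation p = 0.00533, 0.0755 adjusted over the 27 lists), above the non-triple-negative median in 5 of 5 triple-negative tumours. T and NK cell markers were called higher as well (camera adjusted p = 1.61e-08; adjusted p = 0.523 with an estimated correlation), with 18 of 19 measured members higher and none past the threshold adjusted over the list alone. Their score was 0.64 ± 1.32 against -0.23 ± 0.67 (exact permutation p = 0.0728, 0.328 adjusted over the 27 lists), above the non-triple-negative median in 4 of 5 triple-negative tumours and at -1.18 in triple-negative tumour 5. CD247 differed by 0.87 (SE 0.27), CD5 by 1.58 (SE 0.56), CD3E by 1.53 (SE 0.55) and the cytotoxic gene PRF1 by 0.80 (SE 0.32). Without triple-negative tumour 2 the mean difference of the T and NK list was 0.40 rather than 0.87 and the list was still called (adjusted p = 0.00624). With the immune score as a covariate, which contains this list, it was -0.06 (adjusted p = 0.99).

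Markers of most other cell types were not called. Score differences were 0.01 (SE 0.37) for macrophage and myeloid markers, 0.11 (SE 0.32) for fibroblast and collagen markers, 0.13 (SE 0.24) for endothelial, -0.10 (SE 0.59) for adipocyte, 0.33 (SE 0.39) for smooth muscle and pericyte and -0.09 (SE 0.36) for skeletal muscle markers, with exact permutation p of 0.403 or more. Smooth muscle and pericyte markers were called higher without triple-negative tumour 2 (mean difference 0.60, camera adjusted p = 0.00572) or non-triple-negative tumour 6 (0.44, adjusted p = 0.0243), and fell short at 0.12 without triple-negative tumour 4 (adjusted p = 0.709). Endothelial markers ran from 0.027 without triple-negative tumour 1 to 0.24 without triple-negative tumour 5. Fibroblast and collagen markers were called higher without non-triple-negative tumour 6 (0.26, adjusted p = 0.0243), and myeloid markers lower with the immune score, which contains them, as a covariate (-0.63, adjusted p = 1.18e-04). Erythrocyte markers, which come with blood in the tissue, were called higher in camera (adjusted p = 0.0394; adjusted p = 0.607 with an estimated correlation) on 7 measured genes, 6 of them higher and none past the threshold adjusted over the list alone. Of these, the globin genes HBB and HBD differed by 2.29 (SE 1.25) and 0.89 (SE 0.44), ALAS2 by 0.60 (SE 0.48) and CA1 by 0.28 (SE 0.24). That call was lost in 8 of the 19 fits, without triple-negative 3 or 4 or non-triple-negative 1, 2, 3, 6, 12 or 14, with adjusted p of 0.0507 to 0.52, as well as with quantile normalization (adjusted p = 0.0669) and with the lowest 30% of genes left out (0.0987). Interferon-stimulated genes (-0.11, SE 0.44), antigen presentation genes (0.19, SE 0.52), immediate early and handling stress genes (0.00, SE 0.17) and cytosolic ribosomal protein genes (0.08, SE 0.12) were not called in camera with all tumours, with adjusted p of 0.183 or more. Interferon-stimulated genes were called lower without triple-negative tumour 2 (-0.44, adjusted p = 0.0332) and with the immune covariate (-0.63, adjusted p = 0.00125). Antigen presentation genes were called higher without triple-negative tumour 5 (0.59, adjusted p = 4.06e-04) and lower with the immune covariate (-0.55, adjusted p = 3.21e-04). Ribosomal protein genes were called higher without triple-negative tumour 5 (0.17, adjusted p = 0.00671) or non-triple-negative tumour 14 (0.13, adjusted p = 0.0406). Camera called 10 of the 27 lists in all, 6 higher and 4 lower, and as many called lists came up in 59 of 100 splits of the tumours into 5 and 14, the real split included. An estimated correlation, fry's test for a shift in 1 direction and the exact permutation test of the scores each gave 0 lists after adjustment.

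**Figure D3:**
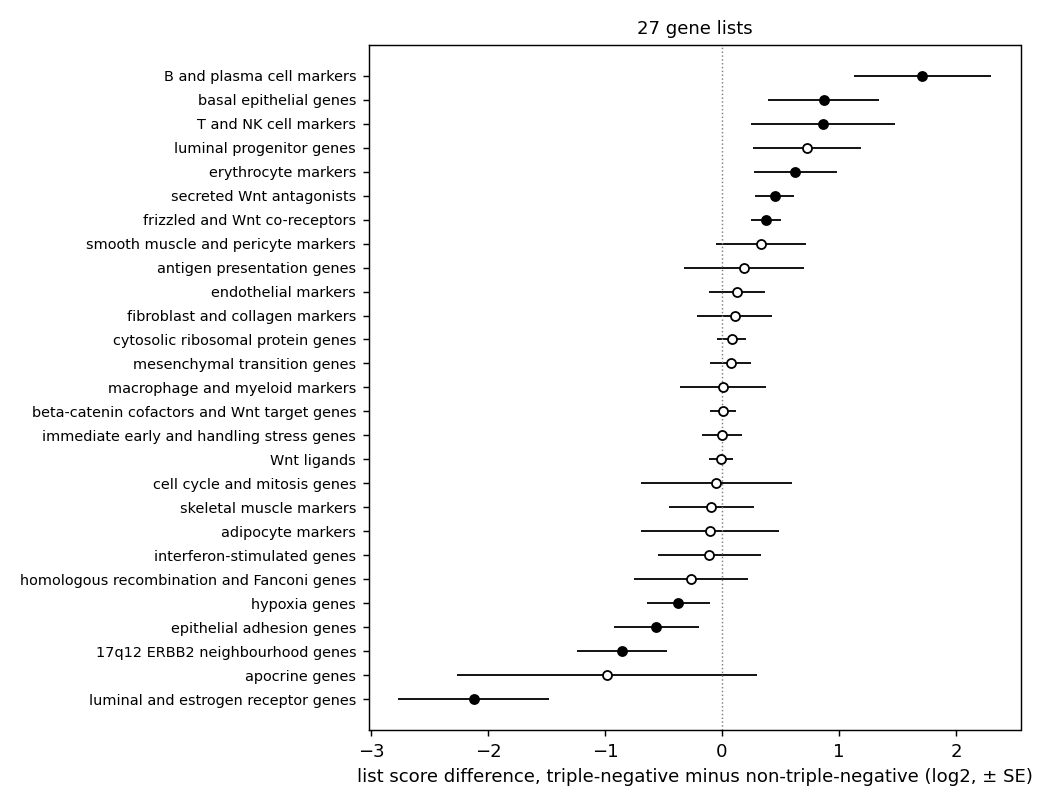
Score difference of 27 gene lists (horizontal axis, log2, triple-negative minus non-triple-negative, ± SE), filled where camera with its preset correlation called the list. B and plasma cell markers stand highest, at 1.71, and luminal genes lowest, at -2.12; none of the 10 filled lists was called with an estimated correlation.

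Proliferation genes were not called with all tumours in the fit. The 35 cell cycle and mitosis genes had a median difference of 0.06 and a mean of -0.05, opposite in sign (camera adjusted p = 0.969). MKI67, the gene of the Ki-67 proliferation antigen, differed by 0.41 (SE 0.80), at 8.19 ± 1.82 against 7.77 ± 1.61, and leaving out 1 tumour moved it between 0.14 (without non-triple-negative 13) and 1.23 (without triple-negative 4). UBE2T (-1.25, SE 0.67), CCNE2 (-0.82, SE 0.59), BUB1 (-1.10, SE 0.89) and ANLN (-0.90, SE 0.74) had the smallest p of the list, and none passed adjusted over the list alone. The result turned on triple-negative tumour 4, whose cell cycle score was -2.03, below every other tumour, against -0.21 to 0.99 in the other triple-negative tumours. Without it the list was called higher by camera at its preset correlation, with a mean difference of 0.45 (adjusted p = 0.0111), and BUB1 moved to 0.29 and ANLN to -0.15. Non-triple-negative tumours 4, 6, 8, 12 and 13, with cell cycle scores of -1.83 to -1.25, stayed in that fit. Removing only the low triple-negative tumour therefore favours a higher difference. UBE2T moved to -0.49 without triple-negative tumour 5, and CCNE2 to -0.40 with array weights. Triple-negative tumour 4 had the highest score of all 19 for the 9 measured apocrine genes, 3.64, against -3.08 to -0.51 in the other triple-negative tumours. Non-triple-negative tumour 12 came next, at 3.05, and had a cell cycle score of -1.67. With all tumours the apocrine list differed by -0.99 (SE 1.28; camera adjusted p = 0.146) and without tumour 4 by -2.08 (camera adjusted p = 3.85e-04), while without triple-negative tumour 2 or 5 it differed by -0.40 (adjusted p = 0.612 and 0.551). In the apocrine list AZGP1 differed by -2.35 (SE 0.78), TFAP2B by -1.85 (SE 1.15), ABCC11 by -2.22 (SE 1.42) and PIP by -1.84 (SE 1.34). Leaving out 1 tumour moved AZGP1 between -3.02 and -1.41, TFAP2B between -2.73 and -1.14, ABCC11 between -3.78 and -1.69 and PIP between -3.36 and -0.91. The homologous recombination and Fanconi genes had a mean difference of -0.26 (camera adjusted p = 0.203), 0.14 without tumour 4, and were called lower without triple-negative tumour 5 (-0.46, adjusted p = 0.0305).

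**Figure D4:**
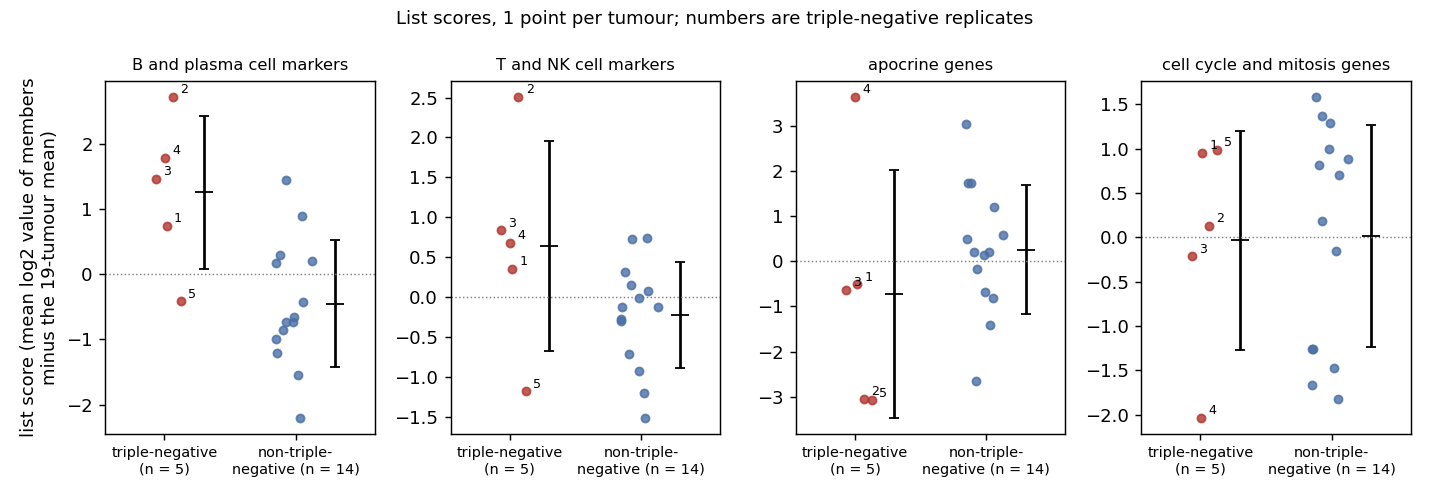
List scores (vertical axes, mean log2 value of the members minus the mean over 19 tumours), 1 point per tumour, with the group mean ± SD as black bars and triple-negative points numbered by replicate. Triple-negative tumour 4 lies highest in apocrine genes, at 3.64, and lowest in cell cycle genes, at -2.03.

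Across the 18394 genes tested, limma called 0 genes higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 719 higher and 976 lower, 1695 together against 919.7 expected by chance. The exact permutation test gave 0 genes adjusted and 1699 unadjusted. Its smallest p, 8.6e-05, was the lowest that 11628 splits allow, and adjusted over all genes by the same test it was 0.264. Passing needed many genes at that lowest value at once, so this 0 decides little. As many as 1695 came up in 7 of 100 splits of the tumours, the real split included. The smallest adjusted p was 0.0674, shared by NEK11, a cell cycle checkpoint kinase (-1.67, SE 0.28), HOXB3, a homeobox transcription factor (-1.48, SE 0.25), and ARFGEF3 (-1.94, SE 0.34). NEK11, HOXB3 and NUDT16 (-1.02, SE 0.18; adjusted p = 0.0726) were higher in all 14 non-triple-negative tumours than in any triple-negative one. DNAH5, a dynein motor of motile cilia, differed by -3.90 (SE 0.70; adjusted p = 0.0726) and CEP15, a centrosomal protein gene, by -2.15 (SE 0.40; adjusted p = 0.0946). On the higher side, CHRM3, a muscarinic acetylcholine receptor, differed by 2.19 (SE 0.42; adjusted p = 0.0987). GFRA3 (3.99, SE 0.88) and GFRA2 (1.29, SE 0.29), co-receptors for ligands of the GDNF family, OLFM2 (1.21, SE 0.26), RCSD1 (1.65, SE 0.38) and PTCHD1 (2.28, SE 0.52) had adjusted p of 0.259 to 0.267. GFRA3 was dim in the non-triple-negative tumours, at 2.73 ± 1.36. Without triple-negative tumour 4 limma called 4 genes higher and 11 lower, among them CHRM3 (2.68, adjusted p = 0.00287), GFRA3 (5.13, adjusted p = 0.00298), ARFGEF3 (-2.29, adjusted p = 0.00287) and CEP15 (-2.60, adjusted p = 0.00287).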

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

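The test that left out single triple-negative tumours to explain the lack of calls was chosen after its result had been seen, and the test on dim genes was not. The 74 named genes and 27 list scores were searched, within the 5 triple-negative tumours, for a tumour standing far from the other 4 by Dixon's ratio. This gave 10 cases, against about 5.05 that a rate of about 1 in 20 would give. That number is a rough guide only. Lists share members with the named genes, related genes move together, and some genes were picked by their p-value on these same tumours. The group of 14 is too large for this rule and was not searched.

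Triple-negative tumour 4 accounted for 5 of the 10. Its MKI67 value was 4.93, against 8.79 to 9.16 in the other triple-negative tumours, its BUB1 value 0.74 against 6.99 to 8.06, and its ANLN value 4.75 against 7.90 to 9.14. ABCC11, an apocrine transporter gene, stood at 12.15 against 3.81 to 5.41, and CEP15 at 7.10 against 4.54 to 5.05.

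Triple-negative tumour 2 had an epithelial adhesion score of -1.76 against -0.14 to -0.05, an interferon-stimulated score of 1.25 against -0.82 to -0.24, and GRB7 at 3.76 against 6.48 to 6.97. Triple-negative tumour 5 had a hypoxia score of 0.46 against -0.65 to -0.34. Triple-negative tumour 1 had P4HA1 at 8.31 against 9.34 to 9.49.

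The absence of genes past the threshold was weighed against 2 explanations. With the dimmer 50% of genes left out, 0 genes passed at an adjusted p under 0.05, but 6 of the 8 genes at an adjusted p under 0.1 are among those left out, so this test, set beforehand to count against noise of low intensities, cannot decide. Leaving out the lowest 30% brought 3 genes past, NEK11, HOXB3 and ARFGEF3, and log2(value + 16), which leaves out no gene, brought 0. Noise of low intensities stays open. Without triple-negative tumour 4, 15 genes passed, while leaving out any other triple-negative tumour gave at most 1, so 1 triple-negative tumour unlike the others may account for part of it. That array had the largest share of values below 1 (3.26%) and a mean correlation with the other arrays of 0.868. The arrays of non-triple-negative tumour 14 (0.868) and triple-negative tumour 5 (0.843) correlated as little or less, and leaving out either brought 0 genes past the threshold. These values cannot tell an unusual tumour from a weaker array. No subgroup of triple-negative tumours is given by the labels, so no biological explanation was tested.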

How the results depend on the processing

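The alternatives log2(value + 16), values as deposited and the exact permutation test for every gene were chosen after seeing the data. FZD7, ESR1, PGR and ERBB2 kept their direction and stayed short of the threshold in every alternative that gave them a value, with leave-one-out ranges of 1.09 to 1.56, -3.76 to -3.14, -2.18 to -1.31 and -1.91 to -1.17. Over the other settings FZD7 ran from 1.13 to 1.32, ESR1 from -3.53 to -1.83, PGR from -1.77 to -1.44 and ERBB2 from -1.72 to -1.20; the -1.83 came from averaging probe sets. With no tumour left out, array weights gave 2 genes higher (CHRM3 and SPIB, the latter named after its value was seen) and 4 lower. Leaving out the lowest 30% of genes gave 3 lower. The other settings gave 0, including the lowest 50% and the exact permutation test, which could hardly pass a gene with 11628 splits. Without single tumours the counts ran from 0 to 4 genes higher and from 0 to 11 lower: 4 and 11 without triple-negative tumour 4, 1 lower (DNAH5) without triple-negative tumour 3, 1 lower (ARFGEF3) without non-triple-negative tumour 8. Genes at an unadjusted p under 0.05 numbered 2601 over all probe sets, where more were tested, and 827 with the lowest 50% left out, where fewer were. Of 74 named genes, none past the threshold with all tumours, 39 moved more than 1.5 times in at least 1 alternative. Those not given with their result were as follows. With log2(value + 16) GFRA2 gave 0.73, DNAH5 -2.20, WIF1 1.89 and DKK1 -1.28. With the immune covariate KIT gave 0.20, ROR1 0.75, MARVELD2 -0.48, RAB25 -0.31, GRHL2 -0.37, CD247 0.54, CD5 0.46, CD3E 0.35, PRF1 0.22, MS4A1 1.58, CD79A 1.16 and BANK1 1.02. With array weights MYC gave 0.34 and CA1 0.037. Without triple-negative tumour 1 CLDN7 gave -0.90 and P4HA1 -0.33, without triple-negative tumour 3 ALAS2 gave 0.34, without triple-negative tumour 4 HBD gave 0.46, and without triple-negative tumour 5 PFKFB3 gave -1.30.

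Camera called 0 lists with an estimated correlation and fry called 0 in its test for a shift in 1 direction and 1, the frizzled list, in its test of either direction. With the immune covariate 8 lists were called: 5 of the 10 called without it, and 3 new ones called lower (interferon-stimulated, antigen presentation and myeloid). It ended the calls of the basal, Wnt antagonist, epithelial adhesion, hypoxia, and T and NK lists, and took the B and plasma list to 0.69, smooth muscle markers to 0.12 and homologous recombination genes to -0.13. The lowest 50% left out gave 1.59 for erythrocyte markers, 0.72 for Wnt antagonists, 0.19 for luminal progenitor genes and -1.55 for apocrine genes. Without triple-negative tumour 5 T and NK markers gave 1.32, and without triple-negative tumour 1 ribosomal genes gave 0.012. With the lowest 50% left out mesenchymal genes were called higher (0.24, adjusted p = 0.0432). Camera's count of lists ran from 6 (without triple-negative tumour 3) to 13 (without triple-negative tumour 5), and list scores past the permutation test from 0 to 2. Luminal, ERBB2 neighbourhood, frizzled, T and NK, and B and plasma lists were called in all 19 fits without 1 tumour. None of these fits leaves out together the 3 non-triple-negative tumours with the highest ERBB2 neighbourhood scores.

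These values changed sign, none of them called with all tumours except the T and NK list; where not stated the cause was not tested. With array weights KRT5 gave -0.16 and KRT14 -0.15. With quantile normalization Wnt ligands gave 0.019 and cell cycle genes 0.0057. With the lowest 30% left out Wnt ligands gave 0.22 (called, adjusted p = 0.0123), adipocyte markers 0.078 and immediate early genes -0.049. With the lowest 50% left out Wnt ligands gave 0.19 (called, adjusted p = 0.0329), myeloid markers -0.0044, skeletal muscle markers 0.15 and immediate early genes -0.080. With the stroma covariate the beta-catenin list gave -0.0037 and myeloid markers -0.016. With log2(value + 16) Wnt ligands gave 0.019, myeloid markers -0.0011 and immediate early genes -0.015. With the immune covariate, built from the T and NK, B and plasma, and myeloid lists, EGFR gave -0.16, the beta-catenin list -0.10, cell cycle genes 0.078, mesenchymal genes -0.11, antigen presentation genes -0.55 (called), T and NK markers -0.060, myeloid markers -0.63 (called), fibroblast markers -0.0043, endothelial markers -0.20, immediate early genes -0.022 and ribosomal genes -0.035.

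Without single tumours, the values that changed sign ranged from -0.23 to 0.70 for KRT14, -1.54 to 0.29 for BUB1, -0.053 to 0.064 for Wnt ligands, -0.062 to 0.062 for the beta-catenin list, -0.30 to 0.45 for cell cycle genes, -0.46 to 0.14 for homologous recombination genes, -0.44 to 0.084 for interferon-stimulated genes and -0.16 to 0.59 for antigen presentation genes. They ranged from -0.25 to 0.21 for myeloid, -0.031 to 0.26 for fibroblast, -0.28 to 0.24 for adipocyte and -0.33 to 0.18 for skeletal muscle markers, and from -0.12 to 0.086 for immediate early genes. No paired analysis was possible because the labels give no shared replicate numbers. Without detection calls, how far dim signals stand above background is unknown.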

Other observations

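The tests of a lower tumour cell share were chosen after the lymphocyte result had been seen. The question about cilia arose from the genes with the smallest p, and its test was written before its score was seen; the other tests below were set beforehand. Triple-negative tumour 4 stood apart in single genes as well. Its brightest probe set on the whole array, at 89879.8 on the deposited scale against at most 2478.4 in any other tumour, was that of HPD, an enzyme of tyrosine breakdown. Other genes that stood out there, all chosen after their values were seen, were UGT2B28, a steroid-conjugating enzyme, at 14.78 against a mean of 6.43 ± 3.08 in the other 18 tumours, ACSM1 at 12.05 against 4.76 ± 2.27, SERHL2 at 12.79 against 6.15 ± 2.40 and the lipoxygenase ALOX15B at 12.69 against 6.38 ± 2.07, the last pair being members of the apocrine list. Among the other tumours UGT2B28 and ACSM1 reached 14.84 and 12.37, above tumour 4, and SERHL2 and ALOX15B reached 11.89 and 11.69, below it. ZP2, at 10.60, and PGC, at 10.27, reached 5.56 and 5.23 at most in any other tumour.

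DNAH5 and NEK11, among the genes with the smallest p, led to a question about motile cilia, whose genes some epithelial cells express. A list of 60 textbook motile cilia genes was written without DNAH5, NEK11 and 2 other genes already seen, and 55 of them were measured. Its score averaged -0.28 ± 0.09 in the triple-negative tumours and 0.10 ± 0.39 in the others, a difference of -0.39 (SE 0.11; exact permutation p = 0.0390), with 5 of 5 triple-negative tumours below the non-triple-negative median. DNAH7 (-1.68, SE 0.55), CFAP69 (-1.35, SE 0.45) and CFAP44 (-0.76, SE 0.28) had the smallest p. Of the 55 genes 37 were lower in mean, 8 at an unadjusted p under 0.05 and 0 adjusted over the list alone, and camera with an estimated correlation gave p = 0.164. Leaving out 1 tumour moved the exact permutation p between 0.0166 and 0.0886, the latter without triple-negative tumour 2. Because the question arose from genes picked on these same tumours, the score is not independent evidence. A gene left out as already seen is on the luminal list, and whether the cilia score follows the luminal difference was not tested. A cilia programme that is lower in triple-negative tumours is a hypothesis that the unadjusted score test fits and the others leave open.

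FZD7, higher in triple-negative tumours adjusted over its list alone but not over all genes, was weighed against the make-up of the tissue. With the stroma score as a covariate 97.9% of the difference remained (1.28, SE 0.33), and with the basal epithelial score 84.6% remained (1.11, SE 0.36). Both values stayed above 50% of 1.31 by more than their SE. Scores of the 3 stroma lists hardly differed between the groups (fibroblast 0.11, endothelial 0.13, adipocyte -0.10). That covariate could hardly move FZD7, so its result cannot decide on stroma. The basal score rests on 14 of 21 list members. Its result argues only against basal cell content, as far as this score measures it, as the whole cause. Whether FZD7 was chosen on these samples is not stated in the sources used here, and that and chance stay open.

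Higher lymphocyte markers might follow from a lower share of tumour cells, which would raise markers of every other cell type alike. The B and plasma score exceeded the mean score of 5 other non-tumour cell types (fibroblast, endothelial, adipocyte, smooth muscle and myeloid) by 1.62 more in triple-negative tumours (exact permutation p = 0.00628). That mean score differed by only 0.10, so the 1.62 largely repeats the B and plasma difference of 1.71. It argues only against a share that raises all these cell types alike as the whole cause. Epithelial adhesion genes had a mean difference of -0.56 (-0.22 without triple-negative tumour 2), so a lower share as part of the cause stays open. For T and NK markers the excess over the 5 types was 0.77 (exact permutation p = 0.0835), too uncertain to decide. There a lower share of tumour cells cannot be told apart from more T and NK cells. A single heavily infiltrated tumour does not account for the B cell difference, since 78.7% of it remained without triple-negative tumour 2, the removal that lowered it most. More B cells in triple-negative tumours remain a hypothesis, because the score did not pass adjusted over the 27 lists (exact permutation, adjusted p = 0.0755).

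Chance groupings of the 19 tumours were compared with the real one over 100 splits into 5 and 14, the real one included. As many genes at an unadjusted p under 0.05 as the real 1695 came up in 7 of the 100, and the highest other split gave 2265, so chance cannot be excluded for that count. As many lists called by camera as the real 10 came up in 59 of the 100, with 19 in the highest other split, so chance cannot be excluded for the number of lists either.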
